A study of Mus musculus with 3 samples.

How the data were processed

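Single-cell gene expression was measured in 3 mouse bone marrow libraries made with the 10x Genomics Single Cell 3' v2 kit and sequenced on a NovaSeq instrument, per the labels' protocols. The marrow came from femora, tibiae, hips and spines, and lineage-negative cells were enriched with antibodies against Ter119, the Ly-6C and Ly-6G antigens, CD11b, CD45R, CD8a and CD5. The groups were LSK (lineage-negative, Sca-1 and Kit positive cells), LK (lineage-negative, Kit positive cells) and TBM (total bone marrow), with 1 library per group. Per the labels, all 3 libraries were obtained with a cell sorter. The labels do not give the number, sex or age of the mice, nor whether Sca-1 positive cells were left out of the LK gate.

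The deposited files hold raw UMI counts per gene and cell barcode, with no normalization, per the file headers and the values themselves, which are whole numbers. Cell Ranger 4.0.0 and the mouse build mm10 are named in the submitters' processing notes. The annotation release, the cell calling setting and any filter on cells before deposition are not given in the sources used here. Gene symbols and Ensembl gene identifiers were taken as the deposited counts pair them. Coordinates come from a GENCODE M21 annotation of GRCm38, which has the same coordinates as mm10 and was matched by gene identifier for 32235 of the genes. That annotation may differ from the release behind the counts.

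All values were computed from those counts with Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9. The files held 8968 barcodes. Barcodes with at least 200 genes and at most 10% mitochondrially encoded UMIs were kept, which left 8824. Scrublet (as built into scanpy, automatic threshold, each library by itself) called 90 of these doublets, and 8734 cells remained. Fewer than 200 genes were seen in 0 LSK, 14 LK and 6 TBM barcodes, and over 10% mitochondrial UMIs in 21, 96 and 23. The removed doublets were 0.280% of LSK, 0.318% of LK and 1.77% of TBM cells, which is under the share that the loading would give, so undetected doublets remain. No correction for free RNA was made.

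Cells of all libraries were clustered together. Counts were scaled to 10000 UMIs per cell and log transformed, 2000 variable genes were taken, and 30 principal components with 15 exact nearest neighbours went into Leiden clustering at resolution 1. Genes of the gate, both cell cycle lists, the immediate early and interferon lists, ribosomal protein and mitochondrially encoded genes, immunoglobulin and T cell receptor segments, Xist and Y-linked genes were left out of the variable genes. Each of the 30 clusters took the name of the cell type list with the highest score (the mean over its genes of log2 CPM standardized across clusters) if at least 3 of its markers were seen in 10% of the cluster's cells. A cluster stayed unnamed where no marker of its list stood among its 10 leading genes, where another list had more markers there, or where a second list scored at least 0.8 as high with 2 or more leading genes. Leading genes were ranked by the ratio of CPM in the cluster to CPM in all other cells, with 10 CPM added to both. These naming thresholds were set after a trial clustering of the same cells had been seen, and they left 6 clusters unnamed, with 4.40% of LSK, 45.3% of LK and 8.02% of TBM cells. A name ends in -like because it rests on RNA markers.

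Levels are CPM, the summed UMIs of a library, or of a class within it, scaled by its total. Ratios between libraries are log2 CPM ratios with exact 95% intervals for the ratio of 2 Poisson counts (conditional binomial), CPM have exact Poisson intervals, and shares of cells have exact Clopper-Pearson intervals. All intervals cover counting error only. With 1 library per group no test between groups is possible, so no p-value or standard error is given, and genes are not counted as changed across the genome. A gene with 0 counts in a library is given as a bound against a floor of 3 counts, and genes with fewer than 3 counts entered list medians at that floor. Shares of cells with a UMI of Mki67 or Top2a were computed after each cell was thinned at random to 2000 UMIs, with cells below that depth left out. The shares given for S100a8, Hbb-bs and the sex-linked genes are over all cells without thinning, so they are not matched for depth.

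For each gene list, the median log2 ratio of members with at least 20 UMIs over both libraries was set against 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries and is no test. Members at least 2-fold higher or lower were counted. Named genes were the 12 largest log2 ratios in each direction with at least 200 UMIs over both libraries, without gate, mitochondrially encoded and ribosomal protein genes and receptor segments. Added to these were up to 4 members with at least 50 UMIs of each list at or beyond the 2.5 or 97.5 percentile, and up to 2 members at least 2-fold against a list's median. Within a class with at least 30 cells in both libraries, the 8 largest ratios in each direction with at least 100 UMIs were named. The text prints part of the genes this rule named. The design, the lists, the naming rule for genes and the first set of alternatives were fixed before the data were examined. Which list medians count as main results was chosen after some of the values had been seen.

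The stem and multipotent progenitor list held Procr, Mecom, Hlf, Fgd5, Mllt3, Hoxb5, Ctnnal1, Slamf1, Tcf15, Meis1, Mycn, Pdzk1ip1, Esam, Hoxa9 and Tek. The lymphoid-primed progenitor list held Flt3, Dntt, Satb1, Notch1, Il7r, Ccr9, Rag1, Cd27, Lsp1, Mn1 and Il12a. The granulocyte-monocyte progenitor list held Mpo, Elane, Prtn3, Ctsg, Ms4a3, Cst7, Gfi1, Cebpe, Prss57, Cebpa, Hdc, Nkg7 and Srgn. The neutrophil list held Camp, Ltf, Ngp, Lcn2, Chil3, Cd177, Retnlg, Mmp8, Mmp9, Cxcr2, S100a8, S100a9, Csf3r, Ifitm6 and Il1b. The monocyte list held Ccr2, F13a1, Ms4a6c, Csf1r, Ctss, Fn1, Klf4, S100a4, Ly86, Irf8, Ahnak and Mpeg1. The conventional dendritic cell list held Cd209a, Itgax, Clec10a, Xcr1, Clec9a, Zbtb46, Naaa, Ifi205, Batf3, H2-Aa, H2-Ab1 and H2-Eb1. The plasmacytoid dendritic cell list held Siglech, Cox6a2, Klk1, Bst2, Rpgrip1, Atp1b1, Upb1, Tcf4, Runx2, Spib and Cd300c. The macrophage list held C1qa, C1qb, C1qc, Vcam1, Hmox1, Axl, Adgre1, Spic, Slc40a1, Mrc1 and Cd163. The megakaryocyte lineage list held Pf4, Itga2b, Gp9, Gp1bb, Ppbp, Vwf, Gp1ba, Gp6, Plek, Itgb3, Treml1 and Rab27b. The erythroid progenitor list held Gata1, Klf1, Epor, Car1, Car2, Blvrb, Ermap, Aqp1, Cldn13, Mt2, Rhd, Sphk1, Gfi1b and Ctse. The erythroblast list held Hba-a1, Hba-a2, Hbb-bt, Hbb-bs, Alas2, Slc4a1, Tfrc, Ahsp, Fech, Rhag and Bpgm. The mast cell and basophil list held Cpa3, Gzmb, Ms4a2, Fcer1a, Mcpt8, Prss34, Cma1, Tpsb2, Mcpt4, Il4, Cyp11a1 and Il6. The eosinophil list held Prg2, Epx, Prg3, Ear1, Ear2, Ear6, Siglecf, Ccr3, Il5ra and Alox15. The pro-B and pre-B cell list held Vpreb1, Vpreb2, Vpreb3, Igll1, Rag1, Rag2, Ebf1, Lef1, Il7r, Akap12, Arpp21 and Sox4. The B cell list held Ms4a1, Cd79a, Cd79b, Ighd, Cd22, Fcer2a, Fcmr, Cd74, H2-Aa, H2-Ob, Iglc2 and Pax5. The plasma cell list held Jchain, Sdc1, Xbp1, Mzb1, Prdm1, Tnfrsf17, Derl3, Iglv1, Igha and Eaf2. The T cell list held Cd3d, Cd3e, Cd3g, Trac, Trbc1, Trbc2, Cd8a, Cd8b1, Cd4, Tcf7, Cd5 and Lck. The NK cell list held Ncr1, Klrb1c, Klre1, Gzma, Klrd1, Eomes, Tbx21, Klrk1, Prf1, Ccl5 and Klra8. The stromal and endothelial cell list held Cxcl12, Lepr, Col1a1, Col1a2, Col3a1, Kdr, Cdh5, Emcn, Sparc, Dcn and Adipoq.

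The S phase list held Mcm2, Mcm3, Mcm4, Mcm5, Mcm6, Mcm7, Pcna, Tyms, Rrm1, Rrm2, Ung, Gins2, Cdc6, Dtl, Slbp, Uhrf1, Rad51ap1, Cdc45, Exo1, Tipin, Dscc1, Blm, Casp8ap2, Usp1, Clspn, Pola1, Chaf1b, Brip1, E2f8, Gmnn, Wdr76, Hells, Rfc2, Prim1, Fen1, Ubr7, Nasp and Polr1b. The G2/M phase list held Hmgb2, Cdk1, Nusap1, Ube2c, Birc5, Tpx2, Top2a, Ndc80, Cks2, Nuf2, Cks1b, Mki67, Tmpo, Cenpf, Tacc3, Smc4, Ccnb2, Ckap2l, Ckap2, Aurkb, Bub1, Kif11, Anp32e, Tubb4b, Gtse1, Kif20b, Hjurp, Cdca3, Cdc20, Ttk, Cdc25c, Kif2c, Rangap1, Ncapd2, Dlgap5, Cdca2, Cdca8, Ect2, Kif23, Hmmr, Aurka, Psrc1, Anln, Lbr, Ckap5, Cenpe, Ctcf, Nek2, G2e3, Gas2l3, Cbx5 and Cenpa. The cyclin-dependent kinase inhibitor list held Cdkn1a, Cdkn1b, Cdkn1c, Cdkn2a, Cdkn2b, Cdkn2c and Cdkn2d. The immediate early and stress list held Fos, Fosb, Jun, Junb, Jund, Egr1, Egr2, Egr3, Ier2, Ier3, Dusp1, Atf3, Zfp36, Btg2, Nr4a1, Hspa1a, Hspa1b, Hspa8, Klf6 and Klf2. The interferon response list held Ifit1, Ifit2, Ifit3, Isg15, Irf7, Oasl2, Oas1a, Mx1, Rsad2, Usp18, Bst2, Ifi27l2a, Xaf1, Rtp4, Ifi203, Ifi47, Igtp, Iigp1 and Zbp1. The antigen presentation class II list held Cd74, H2-Aa, H2-Ab1, H2-Eb1, H2-DMa, H2-DMb1, H2-DMb2, H2-Oa, H2-Ob and Ciita. The primary granule list held Mpo, Elane, Prtn3, Ctsg, Ctsc, Prss57, Serpinb1a, Lyz2, Ctsd and Cd63. The secondary and tertiary granule list held Ltf, Camp, Ngp, Lcn2, Cybb, Chil3, Mmp8, Mmp9, Hp, Orm1, Pglyrp1 and Olfm4. The heme biosynthesis list held Alas2, Alad, Uros, Urod, Cpox, Ppox, Fech, Slc25a37, Slc25a38, Abcb10, Tmem14c and Slc25a39. The glycolysis list held Hk1, Hk2, Gpi1, Pfkl, Pfkp, Pfkm, Aldoa, Tpi1, Gapdh, Pgk1, Pgam1, Eno1, Pkm, Ldha, Slc2a1 and Slc2a3. The cholesterol biosynthesis list held Hmgcs1, Mvk, Pmvk, Mvd, Idi1, Fdps, Fdft1, Sqle, Lss, Cyp51, Msmo1, Nsdhl, Sc5d and Dhcr7. The nucleolus and ribosome biogenesis list held Ncl, Npm1, Fbl, Nop56, Nop58, Dkc1, Nolc1, Nop16, Nop10, Gar1, Nhp2, Rrp12, Bop1, Wdr12, Pes1, Polr1a, Polr1b, Ddx21, Gnl3 and Myc. The hematopoietic transcription factor list held Gata1, Gata2, Gata3, Klf1, Spi1, Cebpa, Cebpb, Cebpd, Cebpe, Irf8, Irf4, Ikzf1, Ikzf2, Tcf3, Ebf1, Pax5, Runx1, Runx2, Runx3, Meis1, Hoxa9, Hoxa7, Hoxa10, Hoxb4, Gfi1, Gfi1b, Tal1, Lyl1, Lmo2, Mecom, Hlf, Fli1, Erg, Nfe2, Myb, Myc, Mycn, Zfpm1, Satb1, Bcl11a, Etv6 and Egr1. The cytokine receptor list held Kitl, Flt3, Csf1r, Csf2ra, Csf2rb, Csf3r, Epor, Il7r, Il3ra, Il6ra, Il6st, Cxcr4, Cxcr2, Ccr2, Tnfrsf1a, Tgfbr1, Tgfbr2, Ifngr1, Ifnar1, Il1r1, Tek, Notch1 and Notch2. Of these, Kitl encodes the ligand of Kit and not a receptor.

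The gate list held Kit, Ly6a, Cd5, Ptprc, Itgam, Cd8a, Ly6g, Ly6c1 and Ly6c2. The 4 further groups were ribosomal protein genes, Hox genes, nuclear respiratory chain genes and mitochondrially encoded genes, each taken by the prefix of the symbol. The 33 lists held 484 genes, of which 482 were found in the files by symbol, with Ahsp and Mx1 as the exceptions. Some list members counted in the list results are not named or reported here. Some genes stand on several lists, so their lists are not independent results. Cd5 and Cd8a are on the T cell list and the gate. Mpo, Elane, Prtn3, Ctsg and Prss57 are on the granulocyte-monocyte progenitor and primary granule lists, and Camp, Ltf, Ngp, Lcn2, Chil3, Mmp8 and Mmp9 are on the neutrophil and secondary granule lists. Cd74, H2-Aa and H2-Ob are on the B cell and class II lists, and H2-Aa, H2-Ab1 and H2-Eb1 on the conventional dendritic cell and class II lists. Il7r and Rag1 are on the lymphoid-primed and the pro-B and pre-B cell lists. Alas2 and Fech are on the erythroblast and heme lists. Hoxa9 and Hoxb5 are on the stem list and in the Hox group, and Hoxa7, Hoxa9, Hoxa10 and Hoxb4 are on the transcription factor list and in the Hox group. The transcription factor list also shares Mecom, Hlf, Meis1, Mycn and Hoxa9 with the stem list, Cebpa, Cebpe and Gfi1 with the granulocyte-monocyte progenitor list, Gata1, Gfi1b and Klf1 with the erythroid progenitor list, and 1 gene each with 7 further lists (Satb1, Irf8, Runx2, Ebf1, Pax5, Egr1 and Myc). The cytokine receptor list shares Flt3, Il7r and Notch1 with the lymphoid-primed list and members with 6 other cell type lists. Polr1b is on the S phase and nucleolus lists and Bst2 on the plasmacytoid dendritic cell and interferon lists.

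The ratio and list steps were tested on simulated counts with the depth of the real libraries, in which 100 genes were changed 2-fold and 100 4-fold. The counts were Poisson draws from the pooled profile of each pair, the model that the intervals assume. How often the intervals hold the true ratio is therefore largely set in advance. Spread between cells and a shift of the whole scale between libraries were not simulated. For LSK against LK (9657 genes), LK against TBM (10001 genes) and LSK against TBM (8908 genes), 100% of the genes changed by a log2 of 1 and 100% of those changed by 2 came out in the right direction with an interval that excluded 0. The intervals held the true ratio for 95.2%, 95.1% and 95.5% of the unchanged genes in that order, for 91%, 97% and 90% of the genes changed 2-fold, and for 98%, 95% and 97% of those changed 4-fold. Of random lists with no change, 7%, 4% and 8% fell beyond the 2.5 and 97.5 percentiles in the 3 comparisons.

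The alternatives were no cell filter, a filter of at least 500 genes and at most 5% mitochondrial UMIs, no removal of doublets, removal of the expected share of doublets (0.8% per 1000 cells), Leiden resolutions of 0.5 and 2, clustering each library by itself and naming each cell from its own highest list. For ratios they were median-of-ratios size factors, totals without the 50 most abundant genes of any library, equal weight for each cell, and list minimums of 1 and 100 UMIs. Thinning to 1000 and 4000 UMIs and no thinning were tried for shares of cells. Chosen after seeing the data were leaving out cells with over 50 Jchain UMIs, leaving out LSK and LK cells of the B lineage, plasma, T, NK and dendritic cell clusters, and giving each cluster its highest list whatever its leading genes.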

Results

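Mouse bone marrow was profiled as 3 single-cell RNA libraries that differ in how the cells were gated. LSK cells carry Sca-1 and Kit and lack mature lineage antigens, a gate that enriches hematopoietic stem cells and multipotent progenitors. LK cells are the lineage-negative, Kit positive progenitor gate, and TBM is total bone marrow. Each gate is a single library, so no difference between gates has a replicate check, and all intervals are 95% intervals for counting error only. After filtering, the LSK library held 1067 cells with 11836820 UMIs and a median of 9688 UMIs and 3080 genes per cell. LK held 3453 cells with 49711898 UMIs (medians of 13654 UMIs and 3420 genes), and TBM held 4214 cells with 21940695 UMIs (medians of 3346.5 UMIs and 1033 genes). The labels state 1070 LSK, 3441 LK and 3984 TBM cells, and the deposited files hold 1091, 3560 and 4317 barcodes. A count of 3 UMIs, the floor used for genes with no UMI, corresponds to 0.253 CPM in LSK, 0.0603 in LK and 0.137 in TBM.

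The most abundant transcripts differed between total marrow and the LSK and LK gates. S100a8 and S100a9, the calprotectin subunits of neutrophils, took 11.8% of TBM UMIs but 0.00391% of LK and 0.00103% of LSK UMIs. Globin genes took 9.10% of TBM UMIs, 0.00129% of LK and 0.00511% of LSK. Ribosomal protein genes took 31.6% of LSK, 30.7% of LK and 15.3% of TBM UMIs, and mitochondrially encoded genes 2.21%, 2.12% and 1.59%. Immunoglobulin and T cell receptor segments took 0.211% of LSK, 0.0156% of LK and 0.851% of TBM UMIs. In LSK, 1 cell with over 50 UMIs of the plasma cell gene Jchain held 0.252% of the UMIs of all genes. The segment share of LSK may rest largely on that cell and is not given without it. The 10 most abundant genes held 27.2% of TBM UMIs, against 7.68% in LSK and 7.19% in LK.

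The genes of the sorted antigens were used to choose the cells, so they check the labels and are no finding. Kit stood at 81.3 CPM in LSK, 34.5 in LK and 7.61 in TBM. Ly6a, which encodes Sca-1, stood at 101 CPM (95.3 to 107) in LSK, 7.72 (6.97 to 8.54) in LK and 30.8 in TBM. Among the depleted antigens, Ly6g was at 0, 0.101 and 237 CPM in LSK, LK and TBM, and Itgam (CD11b) at 2.20, 2.84 and 67.6. Cd8a had no UMI in LSK or LK and 5.29 CPM in TBM, and Cd5 had 0.0845, 0.221 and 1.82 CPM. Ly6c2 remained at 691 CPM in LK, against 22.9 in LSK and 1316 in TBM, while Ly6c1 was under 1 CPM in every library (0.338, 0.865 and 0.957). Ptprc, whose CD45R isoform a 3' kit cannot tell from the others, was at 71.4, 44.4 and 154 CPM.

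Which cell classes does each gate hold? In LSK, 84.3% of cells (81.9% to 86.4%, exact binomial) fell into clusters with a stem and multipotent progenitor signature. Lymphoid-primed progenitor-like cells made up 5.44% (4.15% to 6.97%) and megakaryocyte lineage-like cells 4.12% (3.01% to 5.50%). LK held 15.8% granulocyte-monocyte progenitor-like (14.6% to 17.1%), 14.7% erythroid progenitor-like (13.5% to 15.9%), 9.53% stem-like (8.57% to 10.6%), 8.75% megakaryocyte lineage-like (7.82% to 9.74%) and 5.33% mast cell and basophil-like cells (4.60% to 6.13%). A further 45.3% of LK cells stayed unnamed, nearly all in a cluster led by F13a1, Irf8 and Ms4a6c (24.1% of LK cells) and a cluster led by Cpa3, Cd34 and Ccl9 (21.1%). TBM held 37.0% neutrophil-like (35.6% to 38.5%), 18.4% B cell-like (17.2% to 19.6%), 13.4% pro-B and pre-B cell-like (12.4% to 14.5%), 9.61% erythroblast-like (8.74% to 10.5%) and 9.28% monocyte-like cells (8.42% to 10.2%). The progenitor classes were rare there, with 0.308% stem-like, 0.237% megakaryocyte lineage-like, 1.12% granulocyte-monocyte progenitor-like, 1.59% erythroid progenitor-like and 0.925% mast cell and basophil-like cells. No neutrophil-like, B cell-like or erythroblast-like cell was found among the 1067 LSK or 3453 LK cells, and the exact intervals for 0 cells reach 0.345% and 0.107%. No cluster was named for dendritic cells, macrophages, eosinophils, plasma cells, T cells, NK cells or stroma, and the TBM cells with the strongest T and NK cell scores (3.49%) and dendritic cell scores (1.80%) sat in unnamed clusters.

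These shares depend on the sort and on the clustering, those of the progenitor classes most. Whether they depend on depth was not tested. The stem-like share of LSK was 25.8% at resolution 0.5, 21.3% with LSK clustered by itself, 43.2% with the expected share of doublets removed and 59.8% with each cell named by its own scores. That of LK was 1.53% at resolution 0.5 and 0% with LK clustered by itself. The granulocyte-monocyte progenitor-like share of LK was 34.3% at resolution 2, 47.7% with each cell named by its own scores and 61.0% when every cluster took its highest list.

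**Figure D1:**
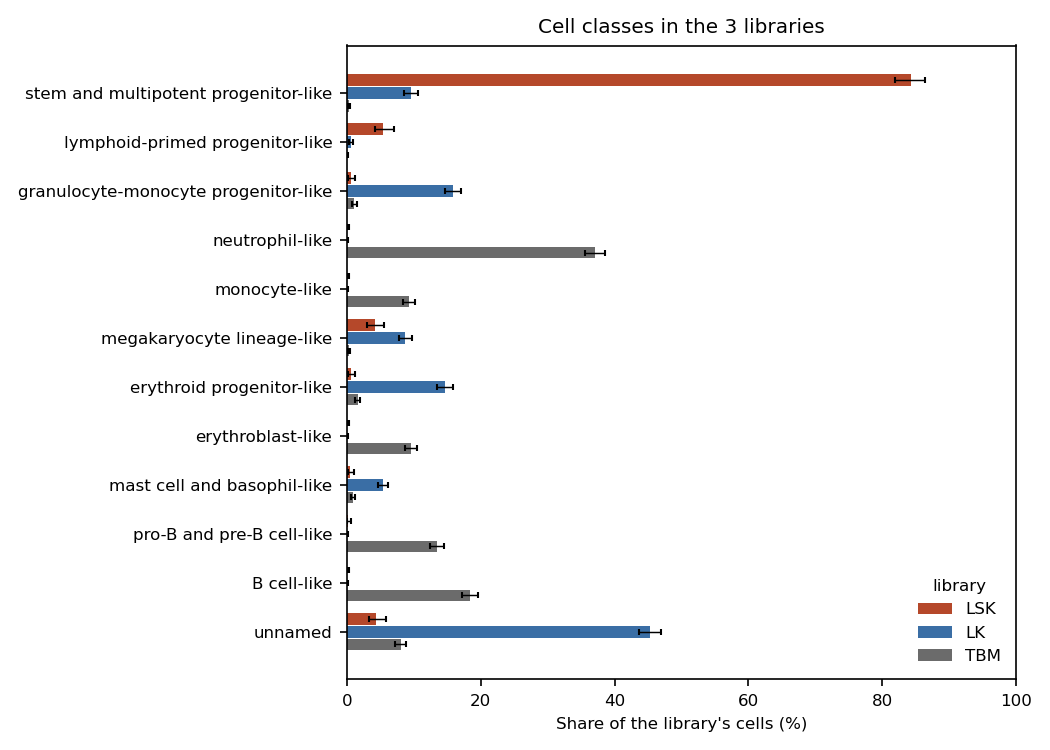
Share of cells (percent, x axis) in each class for the LSK, LK and TBM libraries, with bars for the main clustering and lines for exact 95% binomial intervals. The stem and multipotent progenitor-like class holds 84.3% of LSK, 9.53% of LK and 0.308% of TBM cells.

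LSK against LK asks which transcripts set the Sca-1 positive, Kit positive gate apart from the Kit positive progenitor gate. LSK cells were richer in genes of stem cells, of the homeobox family, of the interferon response and of class II antigen presentation, and poorer in genes of the granulocyte-monocyte, erythroid and mast cell lineages. Mecom, a transcription factor of stem cells (ENSMUSG00000027684, chromosome 3, 29951296 to 30548008 in GRCm38), stood at 74.9 CPM in LSK and 3.82 in LK, a log2 ratio of 4.29 (4.06 to 4.53). Elane, the neutrophil elastase gene (ENSMUSG00000020125, chromosome 10, 79886247 to 79888215), went the other way, with 262 CPM in LSK and 6150 in LK (log2 -4.55, -4.60 to -4.50). All values are on the scale of total UMIs, on which the median of all measured genes was 0.34 for LSK over LK, 0.37 for LK over TBM and 0.67 for LSK over TBM. With size factors these medians were 0.06, -0.03 and -0.00. Medians of random lists matched on expression differed by list, from -0.15 (ribosomal protein genes) to 0.79 (macrophage genes) for LSK over LK. A list whose median lies near that of its matched random lists does not stand apart from other genes.

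All 15 stem and multipotent progenitor genes were at least 2-fold higher in LSK than in LK, with a list median of 2.69 (percentile 100 among matched random lists). Besides Mecom they included Hoxb5 at 4.82 against 0.302 CPM (log2 interval 3.16 to 4.92), Procr, the endothelial protein C receptor (3.90, 3.67 to 4.14), Tcf15 (3.49) and the transcription factor Hlf, at 106 CPM against 11.3 (3.23). Of 16 Hox genes, among them Hoxa9 and Hoxb5 of the stem list, 13 were at least 2-fold higher and 0 lower (median 2.26, percentile 100), Hoxa10 by a log2 of 2.90 and Hoxa5 by 2.33. Further genes with the largest ratios were the homeobox gene Nkx2-3 (4.16), the gonadotropin receptor gene Lhcgr (4.41), Clec1a at 16.4 against 1.03 CPM, the lymphotoxin gene Ltb at 144 against 9.23 CPM (3.96) and Tox (3.94). The lymphoid-primed list had a median of 1.60 (percentile 100, 7 of 11 members at least 2-fold higher), led by Mn1 (3.84), Dntt, the terminal transferase of lymphoid cells (2.89), the cytokine receptor gene Flt3 (1.79) and Lsp1 (1.60).

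Interferon response genes had a median of 1.47 (percentile 100), with 15 of 18 at least 2-fold higher in LSK. They included the interferon-inducible GTPase Iigp1 at 25.8 against 1.29 CPM (4.32, 3.93 to 4.74), Rtp4 (2.31), the antiviral gene Rsad2 (2.23) and Oasl2 (2.09). The class II list had a median of 1.52 (percentile 100, 6 of 10 at least 2-fold higher), with the invariant chain gene Cd74 at 241 against 7.74 CPM (4.96, 4.81 to 5.12), H2-Eb1 (4.40), H2-Aa (4.16) and H2-Ab1 (1.79). Of these LSK UMIs, 16.4% for Cd74 and 17.6% for H2-Eb1 came from a single cell. Immediate early genes, which respond quickly to stimulation, had a median of 0.72 (percentile 100), or 0.34 with equal weight for each cell. Among them the nuclear receptor gene Nr4a1 had a log2 ratio of 2.20, Fosb 1.21 and Fos 0.92.

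Lineage genes were lower in LSK. For granulocyte-monocyte progenitor genes the median was -2.97 (percentile 0, 12 of 13 at least 2-fold lower), with the granule protease gene Ctsg at -3.92, Ms4a3 at -4.26 and the granulocyte transcription factor Cebpe at -4.14. Primary granule genes, 5 of whose 10 members are on that list too, had a median of -1.58 (percentile 0), with myeloperoxidase (Mpo) at 608 against 7736 CPM (-3.67). For erythroid progenitor genes it was -2.11 (percentile 0, 10 of 14 at least 2-fold lower). The Rhesus antigen gene Rhd had 0 UMIs in LSK and 636 in LK (at least 50.5-fold lower), the carbonic anhydrase gene Car1 was at -4.85, and the erythroid transcription factor Klf1 at -3.89, while Car2 was higher in LSK (1.39). Mast cell and basophil genes had a median of -1.27 (percentile 0, 5 of 9 at least 2-fold lower and 3 higher), with Ms4a2 at -2.98 and the carboxypeptidase gene Cpa3 at -2.38, but Prss34 higher in LSK, where 92.1% of its UMIs came from a single cell. Monocyte genes had a median of -1.31 (percentile 0), with F13a1 at -3.27, the receptor gene Csf1r at -2.55 and the transcription factor Irf8 at -2.46, but S100a4 at 2.02 and Klf4 at 1.47. For megakaryocyte lineage genes it was 0.88 (percentile 96.3), with the platelet factor gene Pf4 lower in LSK (-1.02).

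The higher B lineage lists of LSK rested in part on few cells. B cell genes had a median of 4.56, plasma cell genes of 3.29 and pro-B and pre-B cell genes of 2.70 (percentiles 100, 100 and 99.98). A single LSK cell held 98.1% of the Jchain and 96.0% of the Igha UMIs. Without the LSK and LK cells of B lineage, plasma, T, NK and dendritic cell clusters (8 and 6 cells), the medians were 2.38, 1.60 and 0.80, the lymphoid-primed median was 1.03, and Igll1 turned from 2.70 to -1.32. Neutrophil (-1.51), eosinophil (-1.88) and T cell (1.14) medians rest on low counts, and the first 2 turned positive with members of at least 1 UMI (0.20 and 0.48) and the last negative with equal weight for each cell (-0.10).

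For processes common to all cells, list medians differed by less than 2-fold between LSK and LK, though some members differed more. S phase genes had a median of -0.15 (percentile 0.93) and G2/M genes of 0.01 (percentile 4.29), against 0.04 and 0.16 for matched random lists. The nucleolus list was at -0.26 (1.56), respiratory chain genes at -0.31 (0), glycolysis at -0.23 (4.42) and heme synthesis at -0.07 (3.05). Ribosomal protein genes were at -0.03 (99.8) and cholesterol synthesis at 0.44 (71.1). Cyclin-dependent kinase inhibitors were at 0.82 (97.0), with 1 of 5 measured members at least 2-fold higher in LSK (3.24). The transcription factor list, which shares 5 genes with the stem list, was at 0.69 (percentile 100, 12 of 40 at least 2-fold higher and 7 lower) and the cytokine receptor list at 0.31 (30.6). The secondary granule list was at -1.51 (0.010), erythroblast genes at 0.17 (7.16), conventional and plasmacytoid dendritic cell genes at 0.49 (75.6) and 0.63 (89.5), macrophage genes at 0.46 (21.4) and NK cell genes at 0.52 (43.0). Mitochondrially encoded genes were at 0.09 (88.7), or -0.19 with size factors, and fewer than 3 stromal genes were measured.

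Within the stem and multipotent progenitor-like class, 899 LSK cells (median 9273 UMIs) and 329 LK cells (median 7300 UMIs) were compared, and most of the differences between the whole libraries were small. The stem list had a median of 0.55 (percentile 100, 4 of 15 at least 2-fold higher). The interferon, class II, lymphoid-primed and immediate early lists were at -0.02 (percentile 15.4), -0.03 (28.2), -0.11 (5.57) and 0.03 (96.5). Single genes of these lists, chosen after their values were seen, still differed, with Cd74 at 176 CPM (167 to 184) in LSK and 95.1 (83.7 to 108) in LK, and Iigp1 at 28.4 (25.1 to 32.0) and 14.9 (10.6 to 20.4). The granulocyte-monocyte progenitor-like LK cells, a type that should lack Cd74, held 3 UMIs of it (0.0567 to 0.803 CPM; 547 cells, median 19823 UMIs). This class joins 2 clusters in different proportions, and in the cluster led by Mllt3, Mycn and Procr (277 LSK and 53 LK cells) Cd74 stood at 584 CPM (552 to 617) in LSK and 636 (548 to 735) in LK. There the stem list was at 0.04, and the interferon and class II lists were lower in LSK, at -0.41 (percentile 0.020) and -0.45 (percentile 0).

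Some granule genes were lower in LSK within the stem-like class, where the primary granule list had a median of -0.47 (percentile 0) and 3 of 10 members at least 2-fold lower. Elane stood at 4.96 CPM in LSK and 128 in LK (log2 -4.69, -5.17 to -4.24), Ctsg at -2.74, Mpo at -2.15, Ms4a3 at -1.94 and the protease inhibitor gene Cst7 at -1.57. The chemokine gene Ccl9 was at -1.52. Elane stood at about the same level in LK cells of types that should lack it, with 1.01 UMIs per cell (0.921 to 1.11) in the larger erythroid progenitor-like cluster, 1.09 (0.972 to 1.21) in megakaryocyte lineage-like cells and 1.04 (0.920 to 1.16) and 0.925 (0.684 to 1.22) in both stem-like clusters. The Elane difference within classes is therefore not read as expression by these cells. Cst7 had 100 UMIs in the 329 stem-like LK cells and 153 in the 302 megakaryocyte lineage-like LK cells, and Ctsg had 412 and 215. The Cst7 difference, and part of that of Ctsg, is thus not told from background either. The genes with the largest ratios upward were the cardiolipin synthase gene Crls1 at 14.5 against 2.29 CPM (2.66), the ribonuclease gene Rnaset2a at 70.5 against 15.3 CPM (2.21), Nutf2-ps1 (2.08), Gm36839 (1.88), Nptn (1.72) and Gm11808 at 491 against 162 CPM (1.60).

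In megakaryocyte lineage-like cells (44 LSK and 302 LK cells, all of 1 cluster), megakaryocyte genes were lower in LSK, with a median of -1.12 (percentile 0, 7 of 11 at least 2-fold lower) and Pf4 at 441 against 2001 CPM (-2.18, -2.37 to -2.00). The stem list was at 0.54 (percentile 99.2), G2/M genes at 0.39 (percentile 100), S phase genes at 0.33 (percentile 100) and interferon genes at 0.51 (percentile 99.1). Elane (-3.57) and Mpo (-2.28) were lower in LSK here too, with the same limit for Elane. Mpo stood at 2.66 UMIs per cell in these LK cells and at 1.87 in the larger erythroid progenitor-like LK cluster, a type that should lack it, so most of it is not told from background. The linker histone gene H1fx (1.65), Otos (1.60) and Gm11808 (1.55) were higher.

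**Figure D2:**
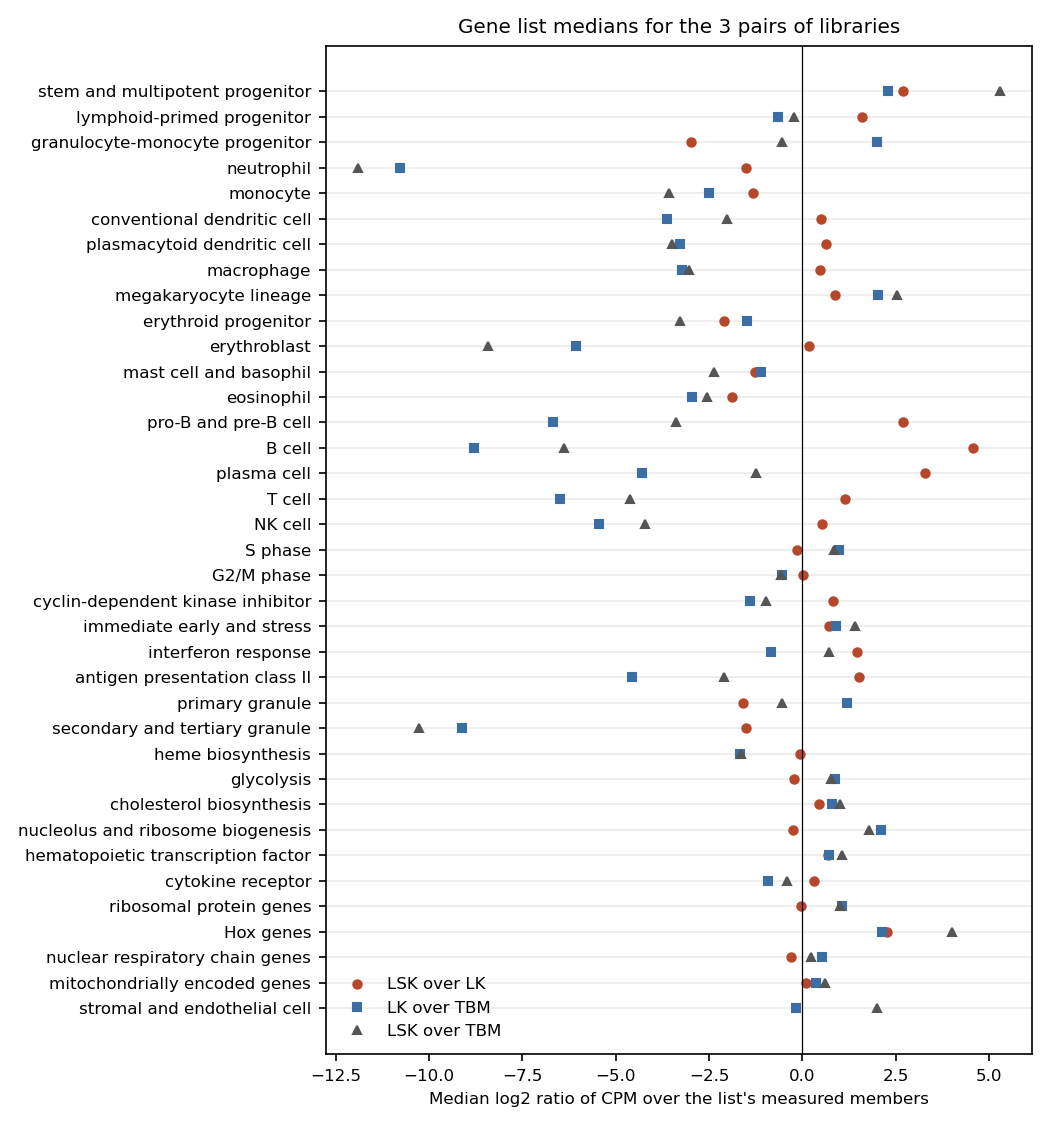
Median log2 CPM ratio (x axis) over the measured members of each gene list (y axis) for LSK over LK (circles), LK over TBM (squares) and LSK over TBM (triangles), on the scale of total UMIs. Stem and multipotent progenitor genes lie at 2.69, 2.30 and 5.29 and neutrophil genes at -1.51, -10.77 and -11.90, and the signs of the mitochondrially encoded list (all pairs) and of the respiratory chain list (LSK over TBM) turn with size factors.

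LK against TBM asks how the progenitor gate differs from unfractionated marrow. LK was richer in genes of stem cells, granulocyte-monocyte progenitors and megakaryocytes and in genes of nucleolus and ribosomes, and genes of most mature blood cells were far lower in it. Mpo (ENSMUSG00000009350, chromosome 11, 87793581 to 87804413) stood at 7736 CPM in LK and 782 in TBM (log2 3.31, 3.28 to 3.33). The beta globin gene Hbb-bs (ENSMUSG00000052305, chromosome 7, 103826534 to 103828096) stood at 3.98 CPM in LK and 39539 in TBM (-13.28, -13.49 to -13.08).

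Of 13 granulocyte-monocyte progenitor genes, 11 were at least 2-fold higher in LK and 1 lower (median 2.01, percentile 100), with Ctsg at 3.04, Cst7 at 2.42 and the proteinase gene Prtn3 at 2.31, but Cebpe at -1.90. The primary granule median was 1.20 (percentile 98.9), with Elane at 2.22 and lysozyme (Lyz2) at -5.06. Stem genes had a median of 2.30 (percentile 100, 10 of 13 at least 2-fold higher), led by Hoxa9 (3.70, 3.27 to 4.17), Esam (3.40) and Meis1, a partner of Hox proteins (3.33), while Pdzk1ip1 was lower (-2.31). The Hox median was 2.13 (percentile 99.97) and the megakaryocyte lineage median 2.03 (percentile 100), with Rab27b at 2.86 and the integrin gene Itga2b at 2.71. Among the largest ratios were the early response gene Egr4 (246 UMIs in LK and 0 in TBM, at least 36.2-fold higher), the signaling inhibitor gene Spry1 (5.08), Cyp2j6 (4.79), Emcn (4.63), the chromatin protein gene Hmga2 (4.54), the chemokine gene Cxcl2 (4.37, 4.15 to 4.61) and the mucin gene Muc13 at 90.3 against 4.74 CPM (4.25).

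Genes of ribosome production were higher in LK, with 19 of 20 nucleolus genes at least 2-fold higher (median 2.09, percentile 100), among them Nop58 at 233 against 43.2 CPM (2.43), Wdr12 (2.42), Polr1b (2.37) and Gar1 (2.29). The ribosomal protein median was 1.05 (percentile 100, 48 of 83 at least 2-fold higher). S phase genes had a median of 0.99 (percentile 99.9, 20 of 40 at least 2-fold higher), with Ung at 2.44 and Mcm6 at 1.74 but Rrm2 at -1.15. G2/M genes went the other way, with a median of -0.54 (percentile 0), Ube2c at -2.18, the proliferation marker gene Mki67 at -1.81 and Nusap1 at -1.73. That median was 0.01 with equal weight for each cell.

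Mature cell genes were lower in LK. Neutrophil genes had a median of -10.77 (percentile 0, 14 of 15 at least 2-fold lower), with Retnlg at -14.64, the lactoferrin gene Ltf at -14.51 (5 UMIs in LK and 51440 in TBM), Camp at -14.02 and S100a9 at -13.93. The secondary granule list, 7 of whose 12 members are on the neutrophil list too, was at -9.12 (percentile 0), with Ngp at -13.91 and Chil3 at -11.98. For erythroblast genes the median was -6.06 (percentile 0, all 13 at least 2-fold lower) and for heme synthesis genes -1.67 (percentile 0), with the heme enzyme gene Alas2 at -11.96. Erythroid progenitor genes were at -1.48 (percentile 0), with Rhd at -4.28 but Car1 at 1.26. The B cell median was -8.80, that of pro-B and pre-B cells -6.68 and that of plasma cells -4.29 (percentile 0 for each), with the receptor component gene Cd79a at -11.66, the B lineage transcription factor Ebf1 at -12.46 and Jchain at -12.61. T and NK cell genes were at -6.48 and -5.44, conventional and plasmacytoid dendritic cell genes at -3.63 and -3.29, monocyte genes at -2.50 and class II genes at -4.56 (percentile 0 for each), with Cd74 at -8.48, Spib at -9.79 and Fn1 at -8.09. In 7 of 13 B cell and 5 of 11 NK cell genes, LK or TBM had fewer than 3 UMIs, so the B and NK cell medians are partly bounds. Floor values also entered the pro-B and pre-B cell (4 of 12) and T cell lists (3 of 12). Macrophage genes were at -3.23 (percentile 0.020), eosinophil genes at -2.95 (0.11) and mast cell and basophil genes at -1.12 (0.60), among which Prss34 was at -8.63 and Cpa3 at 2.37.

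The remaining lists of this pair were mixed. Interferon genes had a median of -0.85 (percentile 0.050), with Ifi27l2a at -5.65 but Iigp1 at 1.82 (0.76 to 3.09). Cyclin-dependent kinase inhibitors were at -1.41 (0.64), with Cdkn2d at -2.46 and Cdkn1a at 1.71. Cytokine receptors were at -0.93 (0.010), with the interleukin receptor gene Il7r at -6.96, and the lymphoid-primed list at -0.67 (0.56), with Flt3 at 1.95. Immediate early genes were at 0.89 (93.7), with Klf2 at -1.66, glycolysis at 0.88 (92.0), cholesterol synthesis at 0.80 (96.7), transcription factors at 0.70 (94.3), respiratory chain genes at 0.52 (34.1) and stromal genes at -0.18 (29.0, 3 measured). Mitochondrially encoded genes were at 0.37 (33.7), or -0.02 with size factors.

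Within classes found in both LK and TBM, immediate early genes were higher in LK each time. Their median was 1.76 in granulocyte-monocyte progenitor-like cells (547 LK and 47 TBM cells, 12 of 17 genes at least 2-fold higher and 0 lower) and 3.98 in erythroid progenitor-like cells (506 and 67 cells, 15 of 18 and 0). It was 1.24 in mast cell and basophil-like cells (184 and 39 cells, 10 of 17 and 0) and 1.32 in the unnamed cluster led by F13a1 and Irf8 (832 and 42 cells, 13 of 18 higher and 1 lower), with a percentile of 100 in each. The stress gene Ier3 stood at 183 against 11.3 CPM in granulocyte-monocyte progenitor-like cells (4.01, 3.13 to 5.08), at 181 against 5.51 in erythroid progenitor-like cells (5.04, 3.91 to 6.49) and at 156 against 7.37 in that cluster (4.40, 3.28 to 5.85). Cxcl2 had 1248 UMIs in the granulocyte-monocyte progenitor-like LK cells and 0 in those of TBM (at least 33.6-fold higher). Egr1, a zinc finger early response gene, stood at 293 against 7.35 CPM in erythroid progenitor-like cells (5.32), and the phosphatase gene Dusp1 in granulocyte-monocyte progenitor-like cells had a log2 ratio of 3.10.

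Maturation genes also differed within these classes. In erythroid progenitor-like cells the LK medians were -4.03 for erythroblast genes, -2.49 for heme synthesis, -1.19 for G2/M and -0.95 for S phase genes (percentile 0 for each), with Hbb-bs at -11.76. In mast cell and basophil-like cells the mast cell list was at -3.63 (8 of 9 at least 2-fold lower in LK), with the protease gene Prss34 at 24.2 against 30728 CPM (-10.31), and S phase and G2/M genes were at 0.81 and 0.90. In granulocyte-monocyte progenitor-like cells the nucleolus list was at 0.73. The secondary granule list was at -5.11 there, but erythroblast genes, which these cells should lack, were at -6.76, so the former is not told from RNA of other TBM cells. LK and TBM cells of these 3 classes came mostly from different clusters, so a class name covers different cells in both libraries. RNA of neutrophils and red cells reached other TBM cells too, with S100a8 UMIs in 98.3% of the B cell-like TBM cells (775 cells, median 1908 UMIs), a type that should lack it, and in 2.37% of the erythroid progenitor-like LK cells (median 7281 UMIs).

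LSK against TBM sets the stem-enriched gate against whole marrow. It shares the TBM library with the comparison of LK and TBM, so both carry the same TBM counts. Stem genes were much higher in LSK, with a median of 5.29 (percentile 100, 14 of 15 at least 2-fold higher). Procr was at 58.5 against 0.547 CPM (6.74, 5.93 to 7.70), Mecom at 74.9 against 0.775 (6.59, 5.91 to 7.38), the adhesion gene Esam at 6.89 and Hlf at 5.86. S100a8 (ENSMUSG00000056054, chromosome 3, 90668978 to 90670035) was lowest in LSK, at 5.24 against 71699 CPM (-13.74, -14.12 to -13.38).

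Other genes far higher in LSK than in TBM were Emcn (7.45, 6.08 to 9.33), a sialomucin gene of endothelium and stem cells, the lipoprotein receptor gene Vldlr (232 UMIs against 0, at least 143-fold higher), Spry1 (6.93), the proteoglycan gene Bgn (6.73) and F11r (6.49). The megakaryocyte lineage list had a median of 2.54 (percentile 99.95), with Itga2b at 2.91. All 14 measured Hox genes were at least 2-fold higher (percentile 100), Hoxa10 by a log2 of 6.11 and Hoxa9 by 5.34, and the transcription factor list was at 1.06 (percentile 99.94). Immediate early genes had a median of 1.41 (percentile 100, 12 of 19 at least 2-fold higher), with Atf3 at 3.14, Ier3 at 280 against 34.4 CPM (3.03), Nr4a1 at 2.84 and Dusp1 at 2.72. All 20 nucleolus genes were at least 2-fold higher (median 1.78, percentile 100), with Polr1b at 2.48 and the growth regulator Myc at 2.38, and the ribosomal protein median was 1.01 (percentile 100). Cyclin-dependent kinase inhibitors had a median of -0.98 (percentile 0.61), with Cdkn2d at -1.88, but Cdkn1c, which is tied to stem cell quiescence, stood at 24.1 against 1.23 CPM (4.29) and Cdkn1a at 2.53. G2/M genes were at -0.57 (percentile 0), with Ube2c at -2.48, and S phase genes at 0.83 (94.3).

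Mature lineage genes were lower in LSK than in TBM. Neutrophil genes had a median of -11.90 and secondary granule genes of -10.28, with Retnlg at -13.16, Wfdc21 at -13.03 and Lcn2 at -12.21. Erythroblast genes were at -8.43, erythroid progenitor genes at -3.27 and heme synthesis genes at -1.64, with Alas2 at least 1577-fold lower (0 against 8769 UMIs) and Klf1 at -5.67. B cell (-6.39), pro-B and pre-B cell (-3.39), T cell (-4.62), NK cell (-4.22), monocyte (-3.58), plasmacytoid dendritic cell (-3.50), macrophage (-3.05) and class II (-2.10) lists were all at percentile 0. In 7 of 12 T cell, 7 of 11 NK cell, 5 of 13 B cell and 5 of 11 plasmacytoid dendritic cell genes, LSK or TBM had fewer than 3 UMIs. Such genes entered at the floor, so these medians are partly bounds. Floor values also entered the eosinophil (4 of 6 measured genes), neutrophil (4 of 15), secondary granule (4 of 12) and erythroblast lists (3 of 13). The floor is 0.253 CPM in LSK and 0.0603 in LK, so for genes at the floor a smaller drop in LSK than in LK may reflect depth. The class II list had no member at the floor in either pair (-2.10, and -4.56 for LK over TBM), so the floor does not explain its smaller drop. Plasma cell (-1.24), conventional dendritic cell (-2.01), mast cell and basophil (-2.36) and eosinophil genes (-2.56) lay at percentiles of 0.21, 0.050, 0.040 and 0.11. Granulocyte-monocyte progenitor genes were at -0.55 (percentile 0.22), with Cebpe at -6.04, Elane at -2.33 and the proteoglycan gene Srgn at 1.47, and that median turned to 0.17 with equal weight for each cell. Primary granule genes were at -0.54 (1.07), lymphoid-primed genes at -0.21 (1.38) with Flt3 at 3.74, and cytokine receptors at -0.41 (0). Interferon genes were at 0.70 (56.4), glycolysis at 0.77 (81.3), cholesterol synthesis at 1.01 (88.8) and stromal genes at 1.99 (93.1, 3 measured). Respiratory chain genes were at 0.23 (3.01) and mitochondrially encoded genes at 0.60 (61.2), and with size factors both turned negative (-0.44 and -0.08).

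The highest shares of cells with Mki67 were those of red cell precursors in TBM. After thinning to 2000 UMIs, Mki67 was seen in 43.5% of erythroblast-like TBM cells (38.6% to 48.5%) and 40.0% of erythroid progenitor-like TBM cells. The share was 20.5% in megakaryocyte lineage-like LSK cells (9.80% to 35.3%, 44 cells) and 19.3% in pro-B and pre-B cell-like TBM cells. Of the pro-B and pre-B cell-like cells only 296 of 565 had at least 2000 UMIs (median of all 2076), so their share describes the deeper cells. Mki67 was seen in 3.38% of the B cell-like TBM cells (1.63% to 6.13%), a type that should seldom divide. Only 296 of 775 B cell-like cells had at least 2000 UMIs (median of all 1908). In stem-like cells Mki67 was seen in 4.34% of LSK (3.10% to 5.88%, median 9273 UMIs) and 3.66% of LK cells (1.90% to 6.30%, median 7300 UMIs), near the share of those B cell-like cells. The latter come from the TBM library, so they do not measure the background of LSK or LK. Summed S phase genes stood at 3929 CPM in LSK and 3961 in LK stem-like cells, against 1200 in B cell-like TBM cells. Summed G2/M genes stood at 4277, 4477 and 1793 CPM in the same order. The topoisomerase gene Top2a, which also marks division, was seen in 12.6% of the LSK (10.5% to 14.9%) and 7.32% of the LK stem-like cells (4.74% to 10.7%), against 4.05% of the B cell-like cells (2.11% to 6.97%). Without thinning, Mki67 was seen in 70.9% of erythroblast-like, 17.4% of LSK stem-like, 15.8% of LK stem-like and 2.19% of B cell-like cells. Among LK classes, mast cell and basophil-like cells had the highest thinned Mki67 share (13.6%, 8.99% to 19.4%), before megakaryocyte lineage-like (7.31%), erythroid progenitor-like (6.99%) and granulocyte-monocyte progenitor-like cells (3.66%). Too shallow for thinning were 0 LSK, 9 LK and 1288 TBM cells.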

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

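The processing was varied for 26 main results (shares of the larger classes and the main list medians) and for the other lists, named genes and shares. The main results gave 175 values that kept their direction and size and 73 that moved. The moved values belong to 23 of the 26 main results. Of the other list medians, 983 values kept direction and size, 213 moved and 12 reversed. Of the named genes, 2635 kept both, 624 moved and 1 reversed. Of the other class shares, 85 kept their size and 44 moved, and of the shares of cells with Mki67 or Top2a 17 kept it and 111 moved. No paired analysis was possible because each gate is 1 library.

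With median-of-ratios size factors every log2 ratio of a pair shifts by the same amount, which is the cause of these changes. For LSK over LK the median became 2.41 for the stem and multipotent progenitor list (2.69 on total UMIs), 1.32 for lymphoid-primed (1.60), -3.25 for granulocyte-monocyte progenitor (-2.97), -0.26 for G2/M (0.01), 1.24 for class II (1.52) and -0.19 for mitochondrially encoded genes (0.09), the last a reversal. For LK over TBM it became 1.62 for granulocyte-monocyte progenitor (2.01), -6.46 for erythroblast (-6.06), 1.70 for nucleolus (2.09) and, reversed, -0.0222 for mitochondrially encoded genes (0.37). For LSK over TBM it became 4.62 for the stem list (5.29), -0.89 for lymphoid-primed (-0.21), 1.11 for nucleolus (1.78) and, both reversed, -0.44 for respiratory chain (0.23) and -0.0772 for mitochondrially encoded genes (0.60). Leaving the 50 most abundant genes out of the totals also shifts all ratios of a pair alike. For LK over TBM it gave 1.64 for granulocyte-monocyte progenitor, -6.43 for erythroblast and 1.72 for nucleolus, and for LSK over TBM -0.58 for lymphoid-primed, 1.41 for nucleolus and, reversed, -0.14 for respiratory chain genes.

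With equal weight for each cell, which lowers the part of cells rich in RNA, LSK over LK gave 2.38 for the stem list, -3.24 for granulocyte-monocyte progenitor, -0.19 for G2/M, 1.16 for class II and, reversed, -0.10 for T cell genes (1.14). LK over TBM gave 2.87 for granulocyte-monocyte progenitor, -5.30 for erythroblast, 2.37 for nucleolus and, reversed, 0.00947 for G2/M (-0.54). LSK over TBM gave -0.76 for lymphoid-primed, 2.08 for nucleolus and, reversed, 0.17 for granulocyte-monocyte progenitor (-0.55). The cause was not tested.

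Without the LSK and LK cells of B lineage, plasma, T, NK and dendritic cell clusters, LSK over LK gave 1.03 for lymphoid-primed, 1.30 for class II and, reversed, -1.32 for Igll1 (2.70). For Igll1 the change comes from the few cells left out, as nothing else differs in this alternative. With list members of at least 100 UMIs, LSK over LK gave 1.02 for lymphoid-primed and 1.24 for class II. With members of at least 1 UMI, the neutrophil (-1.51) and eosinophil (-1.88) medians of LSK over LK reversed to 0.20 and 0.48, as the list then takes in further genes of few counts. After thinning to 2000 UMIs, the stem list within erythroid progenitor-like cells of LK over TBM reversed to -0.38. At resolution 2 the granulocyte-monocyte progenitor list within mast cell and basophil-like cells of LK over TBM reversed from -0.42 to 0.18. The cause of these last 2 was not tested.

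Class shares moved too, and for them the cause was not tested. Without a cell filter the stem-like share was 87.9% of LSK and 13.4% of LK, and LK held 14.4% granulocyte-monocyte progenitor-like, 5.80% megakaryocyte lineage-like, 15.9% erythroid progenitor-like and 4.23% mast cell and basophil-like cells, while erythroblast-like cells were 4.26% of TBM. With at least 500 genes and at most 5% mitochondrial UMIs these were 79.9% (LSK stem-like) and 12.3%, 35.0%, 12.9%, 13.4% and 2.36% of LK in the same order, and TBM held 31.2% neutrophil-like, 14.7% pro-B and pre-B cell-like and 19.8% B cell-like cells. With the expected share of doublets removed, stem-like cells were 43.2% of LSK and 5.49% of LK, and granulocyte-monocyte progenitor-like cells 20.2% of LK. With no doublets removed the latter were 17.6%.

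At resolution 0.5, LSK held 25.8% stem-like and 0% lymphoid-primed progenitor-like cells, LK 1.53% stem-like, 16.5% erythroid progenitor-like and 2.17% mast cell and basophil-like, and TBM 10.8% erythroblast-like cells. At resolution 2, LK held 34.3% granulocyte-monocyte progenitor-like, 12.5% megakaryocyte lineage-like and 2.49% mast cell and basophil-like cells. With each library clustered by itself, LSK held 21.3% stem-like and 2.62% lymphoid-primed progenitor-like, LK 0% stem-like and 18.6% granulocyte-monocyte progenitor-like, and TBM 35.4% neutrophil-like cells. With each cell named by its highest list score, LSK held 59.8% stem-like and 14.1% lymphoid-primed progenitor-like, LK 6.98% stem-like, 47.7% granulocyte-monocyte progenitor-like and 13.1% erythroid progenitor-like, and TBM 35.5% neutrophil-like, 10.4% monocyte-like, 8.47% pro-B and pre-B cell-like and 20.2% B cell-like cells. With each cluster named for its highest list, LK held 61.0% granulocyte-monocyte progenitor-like cells.

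Depth limits what TBM can show. Its median of 3346.5 UMIs per cell leaves 1288 cells too shallow for thinning to 2000 UMIs, against 9 in LK and 0 in LSK. A gene absent from LSK is bounded only at 0.253 CPM, the floor of the smallest library.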

Other observations

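In all libraries Y-linked genes were seen and Xist was rare. The X inactivation RNA Xist was seen in 0.375% of LSK, 0.0579% of LK and 0.119% of TBM cells. LSK held 5 Xist UMIs in 4 cells and LK 3 in 2 cells. TBM held 29 in 5 cells, with 8 in 1 neutrophil-like and 8 in 1 erythroblast-like cell, so a few TBM cells carried more of it. The Y-linked genes Eif2s3y and Ddx3y were seen in 54.8% and 36.0% of LSK, 58.2% and 30.1% of LK and 23.2% and 9.82% of TBM cells, where depth is lower.

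A few LSK and LK barcodes carried transcripts of other lineages, and whether they are cells that passed the gate or doublets was not tested. The LSK library held 1 cell with over 50 Jchain UMIs, a plasma cell gene, and that cell held 0.252% of its UMIs. Cells of B lineage, plasma, T, NK and dendritic cell clusters numbered 8 in LSK, 2 of them pro-B and pre-B cell-like, and 6 in LK and held 1.13% and 0.0802% of the UMIs.

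RNA of abundant cells was spread over the TBM library. S100a8, a neutrophil gene, had UMIs in 98.3% of B cell-like and 97.2% of pro-B and pre-B cell-like TBM cells (median depths 1908 and 2076 UMIs), types that should lack it, and Hbb-bs in 92.1% of the B cell-like cells. Low levels of neutrophil or globin genes in any TBM class were therefore not counted as a finding.

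Immediate early genes were higher in LK than in TBM in 4 classes or clusters, and all tests of this were chosen after seeing the result. A different mixture of classes could raise the list in whole libraries. The lowest median within the 4 was 1.24, so a mixture between classes does not account for the difference within them. That value restates the observation and is no separate test. It cannot speak on a mixture of clusters within a class. Free RNA taking a share of the TBM totals would lower all genes alike. The lowest percentile against matched random lists was 100, so a shift of all genes alike does not account for the difference. That percentile was known when the test was chosen, so it is no separate evidence. Handling during the sort could induce these genes in LSK as well, where the median over TBM was 1.41, but the labels say that all 3 libraries were obtained with a cell sorter, so handling stays open. Other states of the LK cells are possible too, since in 3 of the 4 the libraries fill different clusters.

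Granule genes were found in stem-like, erythroid progenitor-like and megakaryocyte lineage-like LK cells, and the tests used here were chosen after seeing the result. Free RNA would give these classes about the same number of UMIs per LK cell, and for Elane the highest over the lowest of clusters 1, 8, 10 and 11 was 1.17, so free RNA is a candidate source of Elane in them and of its difference from LSK. For Mpo it was 4.61, with 5.57 UMIs per cell in stem-like cluster 1 and 1.21 in cluster 11, which argues against free RNA as the only source of Mpo and leaves expression by stem-like cells open. Doublets would put the RNA into few cells, but the 5% of stem-like LK cells with most Elane held 16.7% of it, which argues against doublets. A comparison planned with cluster 15, at 1.95 Elane and 14.0 Mpo UMIs per LK cell, was set aside after its values were seen because its mast cell and basophil-like cells make granules.

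In cluster 1, the larger stem-like cluster, 75 genes were at least 2-fold higher in LSK than in LK, and the test of cell states was chosen after the result while the test of a library-wide difference was fixed before. Another mixture of cell states confined to cluster 1 would not carry these genes into other clusters. Their median was 0.92 in cluster 3, 0.92 in cluster 10 and 0.51 in cluster 11, the other stem-like cluster. The gate can select states within every cluster, though. In cluster 10 the stem list was higher and the megakaryocyte list lower in LSK, so this test cannot decide on a mixture of states. A difference that belongs to the LSK library would leave LK and TBM alike, and in cluster 2 their median for LK over TBM was -0.53. That value lies just outside the bound set for such a difference and short of that set against it, so a library-wide origin stays open. A gene such as Gm11808, higher in LSK in both the stem-like (1.60) and the megakaryocyte lineage-like class (1.55), might therefore reflect the library and not the gate.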
